A study of Homo sapiens with 16 samples.

How the data were processed

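Gene expression was measured by RNA sequencing in Hs578 and TT642 cells, as parental cells and as derived lines that carry a doxycycline-inducible short hairpin RNA (shRNA) against PRRX1. Per the labels' protocols, total RNA was extracted with RNeasy kits, and libraries of polyadenylated RNA were made from 500 ng with the stranded TruSeq kit. Doxycycline was given at 3 µg/ml per the labels. The treatment time is not given in the sources used here.

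The authors deposited a table of raw read counts per gene symbol for 20114 genes, which held whole numbers with totals that differed between libraries. The authors also deposited FPKM values, which scale fragment counts by transcript length and library depth, for 20111 genes, and 3 genes stood only in the count table. The genome build was hg19 per the submitters' processing notes. The aligner, the counting tool, the annotation and whether counting used strand are not given in the sources used here. Reads of near-identical copies, such as ribosomal protein genes and their pseudogenes or mitochondrial genes and their nuclear copies, could therefore have been split or dropped in a way that is unknown, and so could reads of overlapping or antisense genes. Genes are identified by the symbols in the files, and no coordinates were used.

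Column names matched the sample titles, so each column was assigned to 1 library. The 16 libraries fell into 8 groups by line, hairpin status and doxycycline. Hairpin groups held 3 libraries, 1 per hairpin, and parental groups held 1. Total counts ran from 13461527 to 24672906 per library. No 2 libraries agreed within sampling noise, with a lowest chi-square per degree of freedom of 5.35, so none was treated as a duplicate. Of the 20114 genes, 2457 had no count in any library. The intervals given for PRRX1 are exact binomial intervals at the 95% level and cover counting error only.

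The counts were tested with edgeR 4.0.16 in R 4.3.3, using its quasi-likelihood test with TMM scaling, the default expression filter on the 8 groups and robust moderation. The filter left 14035 genes. All 16 libraries were fitted together with 1 mean per group, which left 8 residual degrees of freedom, and the single parental libraries were assumed to vary like the hairpin groups. These tests of genes were two-sided, p-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Levels are TMM-scaled CPM (counts divided by the effective library size), and per-pair log2 ratios used a prior count of 2. The 7 comparisons were doxycycline against none in the hairpin lines of Hs578, the same in TT642, the mean and the difference of these effects, doxycycline in parental cells, the hairpin effect net of the parental doxycycline effect, and hairpin lines against parental cells without doxycycline. The last 3 were means over both lines.

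For the gene groups, 32 lists were fixed before the data were examined, as were the design, the alternatives below and the rule for naming genes. The lists cover ribosomal proteins, the nuclear and mitochondrial respiratory chain genes, hypoxia and glycolysis, the amino acid and endoplasmic reticulum stress responses, matrix proteins and matrix enzymes, fatty acid and cholesterol synthesis, immediate early, inflammatory and interferon genes, S phase, mitosis, p53, TGF-beta, YAP and Wnt targets, actin and smooth muscle genes, SWI/SNF subunits, epithelial, mesenchymal, basal and luminal breast genes, mesenchymal transcription factors, and markers of fat, bone and cartilage, skeletal muscle, neural, blood and endothelial cells. Each list was tested with camera from limma 3.58.1 on log2 CPM with the preset correlation between genes, adjusted over the 32 lists of a comparison. Camera with an estimated correlation and fry were run beside it. Camera compares a list with all other genes, whereas fry asks whether the genes of a list move one way on balance. The rule named PRRX1, then the called genes with the largest log2 fold changes among those with a mean log2 CPM of at least 2 and the same direction in all compared hairpins or lines (6 per direction within a line, 5 otherwise), and up to 3 called members of each list that was called or had at least 3 called members. Where fewer than 10 genes passed, the genes with the smallest p were added up to 10. Y-linked genes, XIST, TSIX and clone names were left out. PRRX2 and SMARCB1 were named in any case. Some genes that the rule takes are not reported here.

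Libraries with the same hairpin number in their titles were taken to come from the same derived line, so the numbers pair libraries with and without doxycycline. The deviations from the group means of same-numbered libraries correlated at 0.27, 0.04 and 0.05 in Hs578 and at 0.51, 0.41 and 0.42 in TT642. Those of different-numbered libraries correlated at -0.22 to 0.19 in Hs578 and at -0.39 to -0.02 in TT642. The pairing thus shows in the values of TT642, but not in those of Hs578 hairpins 2 and 3. A fit with the derived line as a replicate block, which left 4 residual degrees of freedom, was run beside the fit without it.

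The alternatives were DESeq2 1.42.0, relative log expression scaling, no filter on low counts, a filter of at least 1 CPM in at least 3 libraries, the block, a fit to the libraries of a comparison alone, a fold threshold, limma on log2(FPKM + 1) and on log2(FPKM + 0.1) over genes with a mean FPKM of at least 1, and leaving out each hairpin or single hairpin library in turn. TMM scaling without mitochondrial genes, a fit without robust moderation and tests of each line alone were added after the data were seen.

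Other splits of the hairpin libraries were counted, 10 within each line and 80 over both, and the 80 were drawn after a first run with 25. The 80 leave out the split that exchanges the labels of 1 line alone. All 32 splits over both lines that part the 6 pairs, and the 20 of TT642 with the real split kept in Hs578, were added when most of their counts had been seen. The tests were tried on simulated counts with planted changes before use. For the hairpin effect in Hs578, over 13884 simulated genes, edgeR recovered 74.6% of changes of 1.5-fold, 88.1% of 2-fold and 100% of 4-fold changes, and 8.38% of its calls were false. For TT642, over 13871 genes, it recovered 56.7%, 91% and 97% at the same folds, and 6.32% of its calls were false. For the effect net of doxycycline, over 13852 genes, the shares were 29.9%, 85.1% and 98.5%. Changes were planted only in genes with an expected count over 20 in both lines, and equally in every library of a group. These shares therefore do not hold for genes of lower count or for effects that vary between hairpins. The real fall of PRRX1 in TT642, of 4.08-fold, was not called by edgeR (adjusted p = 0.17). A planted list, made of the genes planted upwards, was found in the planted direction, and none of the 32 other lists was called. The simulated genes varied independently, whereas the estimated correlation was 0.91 among the real ribosomal protein genes. The simulation therefore does not show how often the preset correlation gives false calls for lists whose genes move together.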

Results

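RNA was sequenced from Hs578 and TT642 cells in which an shRNA against PRRX1 can be switched on with doxycycline. PRRX1 encodes a homeobox transcription factor of mesenchymal cells. Hs578 is a breast cancer line. TT642 carries a rhabdoid tumour source label, although the series design describes both lines as triple-negative breast cancer, the class without hormone receptors or HER2. Each line was sequenced as parental cells without a hairpin and as 3 derived lines with 1 hairpin each, with and without 3 µg/ml doxycycline, which gave 16 libraries. Total counts were 13461527 to 19139654 in Hs578 libraries and 15265227 to 24672906 in TT642 libraries. Mitochondrial transcripts took 2.16% to 2.79% of the counts in the Hs578 libraries without doxycycline, and 3.18%, 4.27% and 5.44% in the induced Hs578 hairpin lines. The replicates of a hairpin group, numbered 1 to 3 in the sample titles, were read as 3 different hairpins, the same in both lines. Nothing in the labels says whether they came from separate cultures, so p-values measure only the spread between these samples, which may be partly technical.

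PRRX1 was first examined in every library, to see how far each hairpin lowered its target. Parental cells held 290 CPM (counts scaled to library size) of PRRX1 without and 298 CPM with doxycycline in Hs578, and 1480 and 1530 CPM in TT642, so that 103% of the level was left in each line (95% intervals 98.8% to 107% and 102% to 105%). In Hs578, hairpins 1, 2 and 3 left 12.7% (11.6% to 13.9%), 32.1% (29.8% to 34.6%) and 19.5% (18.1% to 20.9%) of the uninduced level. In TT642 the hairpins with the same numbers left 21.8% (21.1% to 22.5%), 13% (12.6% to 13.5%) and 39.4% (38.6% to 40.3%). The group mean went from 260 ± 32.3 CPM to 53.6 ± 18 CPM in Hs578 and from 1310 ± 98.2 to 320 ± 172 CPM in TT642 (SD, n = 3). PRRX1 was thus lower in all 6 induced hairpin lines.

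**Figure D1:**
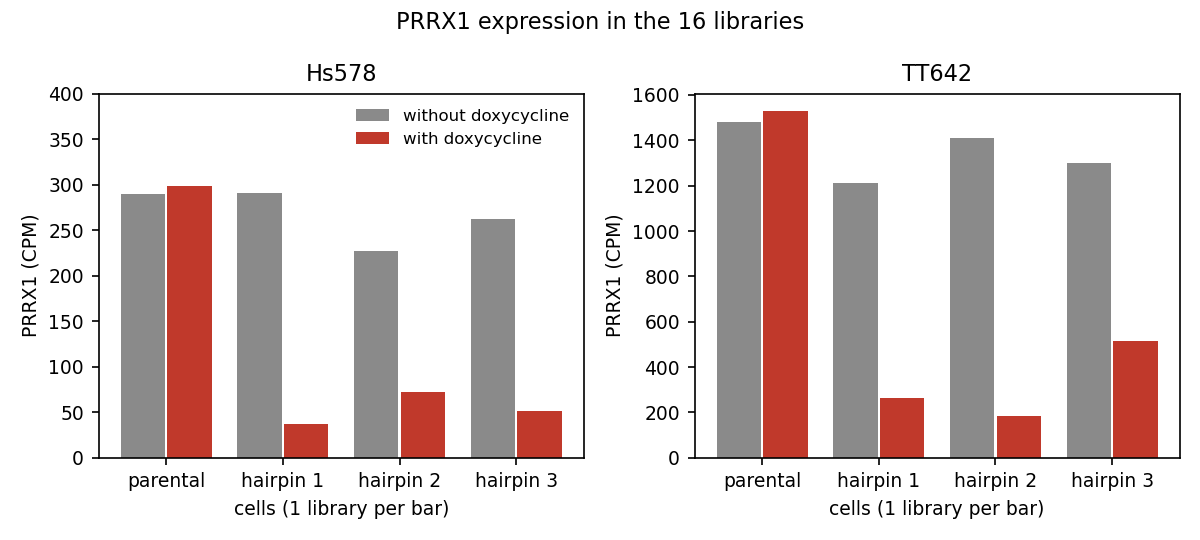
PRRX1 level in CPM (scaled counts) in each of the 16 libraries, with 1 bar per library, grey without and red with doxycycline; the vertical scales of the Hs578 and TT642 panels differ. Parental cells hold 290 and 298 CPM in Hs578 and 1480 and 1530 CPM in TT642, and each induced hairpin line lies below its uninduced partner.

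By edgeR, the fall of PRRX1 in Hs578 was called (log2 fold change -2.28, SE 0.37, adjusted p = 0.0022), although not without hairpin 1 (adjusted p = 0.06, over a range of 4.7e-08 to 0.06 across the alternatives). In TT642 the change was of similar size (-2.03, SE 0.36) but missed the threshold over all genes (adjusted p = 0.17, and 6.7e-05 by DESeq2, over a range of 6.7e-05 to 0.87 across the alternatives). Over both lines it was called (-2.15, SE 0.25, adjusted p = 0.0019). The effects of the 2 lines did not differ by the test of the difference (-0.25, SE 0.49, adjusted p = 0.81), and the sign of that difference turned to 0.3 without hairpin 3 and to 0.27 without the induced TT642 hairpin 3 library. An exact permutation test of 3 against 3 libraries gave p = 0.1 in each line, two-sided, the smallest value it can give. PRRX2, the paralogue of PRRX1, was not called in Hs578 (0.78, SE 0.36, adjusted p = 0.13) or TT642 (-0.47, SE 0.34, adjusted p = 0.83).

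In Hs578 hairpin lines, the question was which genes change when PRRX1 is lowered. Genes with large rises included several of the matrix and of contractile cells. COL1A1, the main collagen of connective tissue, rose from 2180 ± 146 to 9230 ± 2800 CPM (SD, n = 3; log2 fold change 2.08, SE 0.63, adjusted p = 0.036). TGFBI, a matrix protein induced by TGF-beta, rose from 725 ± 30.2 to 2800 ± 595 CPM (1.95, SE 0.23, adjusted p = 0.00044), and TAGLN, an actin-binding protein of smooth muscle, from 66.1 ± 15 to 313 ± 163 CPM (2.24, SE 0.34, adjusted p = 0.0019). The hypoxia-induced carbonic anhydrase CA9 rose by 3.07 (SE 0.5), the cytokine IL32 by 2.53 (SE 0.3) and COL5A3 by 1.92 (SE 0.48) on the log2 scale. The genes that fell most included the immediate early factors FOSB (-4.47, SE 0.85), FOS (-3.06, SE 0.72) and ATF3 (-2.88, SE 0.55). IGFBP1, which binds insulin-like growth factors, fell to 2.51 ± 0.793 from 14 ± 3.89 CPM, GDF15, a stress-induced cytokine, to 5.75 ± 1.68 from 24.2 ± 11.3, and VAT1L to 4.7 ± 1.5 from 16.4 ± 1.18.

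In total 2139 genes rose and 1979 fell in Hs578 at an adjusted p under 0.05, 211 and 203 of them at least 2-fold. Which direction held more genes varied between settings: 1904 rose and 2260 fell with relative log expression scaling, 1886 and 2280 by DESeq2, 1354 and 2990 by limma with log2(FPKM + 1), and 1281 and 2809 with log2(FPKM + 0.1). Slightly more genes also fell with the replicate block (2401 and 2461), with the Hs578 libraries alone (1953 and 2021) and without hairpin 2 (1354 and 1444) or hairpin 3 (376 and 464). The count of 4118 depended on single libraries. It was 2678 without hairpin 1, 840 without hairpin 3, 2253 without the uninduced hairpin 1 library, and 2714 and 2680 without the induced hairpin 2 and hairpin 3 libraries. Of the 81 called genes named by the rule, 30 were called whichever hairpin or library was left out, among them IL32, TAGLN, TGFBI, IGFBP1, GDF15 and VAT1L. The others include 19, 21 and 45 genes lost without hairpins 1, 2 and 3, with an adjusted p up to 0.51, and 4 to 22 lost without a single library. The calls of COL1A1, COL5A3, FOSB, FOS, ATF3 and CA9 were lost without at least 1 hairpin (adjusted p = 0.24 for COL1A1 and 0.056 for CA9 without hairpin 3, 0.065 for COL5A3, 0.11 for FOSB, 0.18 for FOS and 0.08 for ATF3 without hairpin 1). COL1A1 was also not called with no filter on low counts (0.054), nor COL5A3, FOSB and FOS with the Hs578 libraries alone (0.057, 0.05 and 0.08). Of genes named from the lists below, FABP4, PGR and SOX9 were not called by DESeq2 (0.13, 0.074 and 0.14), nor were CDT1, CNN1, TGFB1I1, AURKB, IFI27, SMARCB1, SPINT1, LSR, KRT7, LEF1 and SOX9 with at least 1 pseudocount of the FPKM (0.055 to 0.78). ERBB3 was not called with the Hs578 libraries alone (0.078), nor EN1 (0.055), ISG15 (0.067), SPINT1 (0.06), LSR (0.054), KRT7 (0.051) and SOX9 (0.072) with no filter. SPINT1 and KRT7 were not called with relative log expression scaling (0.052 and 0.054), nor PGR and KRT7 without robust moderation (0.052 for both).

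Parental Hs578 cells, which carry no hairpin, showed many of these shifts with doxycycline in their single pair of libraries. COL1A1 went from 2040 to 6600 CPM, CA9 from 2.24 to 17.2, IL32 from 4.82 to 17.4, TGFBI from 713 to 1440, FOS from 111 to 10.3 and IGFBP1 from 15.4 to 4.18. VAT1L stood at 14.3 and 14.8 CPM, SCD at 3250 and 3670 and SQLE at 349 and 375, where the induced hairpin lines were lower. Of the 4118 genes, 3429 (83.3%) had the same sign in the parental pair (Pearson 0.71, Spearman 0.72, across genes, which are not independent replicates). Without doxycycline, pairs of Hs578 libraries matched the hairpin effect in sign, in the better orientation of each pair, for 58.4% to 82.1% of these genes. Each such pair holds an uninduced hairpin library that also enters the hairpin effect.

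Matrix genes rose as groups in Hs578 by camera with its preset correlation, but not with an estimated correlation (adjusted p = 0.596 for matrix proteins and 0.366 for matrix enzymes). The actin and smooth muscle list was not called. Of 38 collagens and matrix proteins, 18 rose and none fell over all genes (19 and 1 adjusted over the list alone; median 0.49, camera adjusted p = 0.000908), among them TNC, an adhesion-modulating glycoprotein (1.89, SE 0.26). Of 27 matrix enzymes, 13 rose and none fell (13 and 1 adjusted over the list alone; median 0.51, adjusted p = 0.000247), including the collagen chaperone SERPINH1 (1.38), the procollagen protease BMP1 (1.21) and the prolyl hydroxylase P4HA3 (1.17). Among 21 actin and smooth muscle genes, 7 rose, such as CNN1 (2.01, under 1 CPM) and ACTA2 (1.87), and 2 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.0947, and 0.737 with an estimated correlation). Of 21 TGF-beta targets, 4 rose, with LTBP3 (0.62) and TGFB1I1 (0.6) beside TGFBI, and 3 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.35). The parental pair had medians of 0.79 for matrix proteins and 0.7 for matrix enzymes, above those of all 3 hairpins (0.18, 0.48 and 0.61 for matrix proteins, and 0.25, 0.61 and 0.57 for matrix enzymes).

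Lists of translation and energy metabolism genes were also called as higher in Hs578, although not with an estimated correlation (adjusted p = 0.6 for the nuclear respiratory chain list and 0.596 for the other 3 lists). Of 33 ribosomal protein genes, 31 rose (33 adjusted over the list alone; median 0.47, camera adjusted p = 9.39e-11), for example RPL18 (0.77, SE 0.15), RPL35 (0.75) and RPS15 (0.73). Of 33 nuclear respiratory chain genes, 18 rose and 1 fell (22 and 1 adjusted over the list alone; median 0.34, adjusted p = 4.57e-06), with NDUFA2 (0.82), COX4I1 (0.67) and NDUFB8 (0.67) leading. Of 13 genes of the mitochondrial genome, 12 rose (12 adjusted over the list alone; median 0.85, adjusted p = 2.23e-05), led by MT-CO2 (1.13), MT-CYB (1.1) and MT-CO3 (1.06), with medians of 0.21, 0.92 and 1.46 in hairpins 1, 2 and 3 and 0.67 in the parental pair. Of 29 hypoxia and glycolysis genes, 14 rose and 2 fell (16 and 2 adjusted over the list alone; median 0.4, adjusted p = 9.44e-05), including ANKRD37 (1.3) and the lactate transporter SLC16A3 (0.81). The parental pair had a ribosomal median of 0.47, with all 33 genes higher, against 0.35, 0.37 and 0.63 in hairpins 1, 2 and 3. Its nuclear respiratory chain median was 0.18 (hairpins 0.28, 0.26 and 0.4) and its hypoxia median 0.3 (hairpins 0.31, 0.66 and 0.19). How reads shared with pseudogenes or nuclear copies of these genes were counted is not given in the sources used here.

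Some members of the amino acid stress, immediate early, lipid synthesis and adipocyte lists fell in Hs578. Camera called these 5 lists as lower, but not with an estimated correlation (adjusted p = 0.6 for the amino acid list, 0.635 for the immediate early list and 0.366 for the lipid and adipocyte lists). Of 32 amino acid stress response genes, 14 fell and 1 rose (15 and 1 adjusted over the list alone; median -0.32, camera adjusted p = 9.44e-05). Those that fell included SESN2 (-1.3, SE 0.13) and the cystine transporter subunit SLC7A11 (-1.22, SE 0.11). SLC7A11 also fell in the parental Hs578 pair, with the levels given below for doxycycline alone. Of 17 immediate early genes, 6 fell (6 adjusted over the list alone; median -1.02, adjusted p = 0.00259), with medians of -1.32, -1.15 and 0 in hairpins 1, 2 and 3, and this list was not called without hairpin 1 (adjusted p = 0.083) or with log2(FPKM + 0.1) (0.057). Its median was -0.57 in the parental pair, where those of the other lists called as lower ran from -0.19 (adipocyte) to -0.05 (amino acid stress and cholesterol). Of 24 cholesterol synthesis genes, 14 fell and 1 rose (16 and 1 adjusted over the list alone; median -0.36, adjusted p = 0.00059), including STARD4 (-0.82) and SQLE (-0.68). Of 11 fatty acid synthesis genes, 5 fell (8 adjusted over the list alone; median -0.25, adjusted p = 0.00059), with the desaturase SCD (-0.7), FASN (-0.62) and ACACA (-0.58). Among 5 adipocyte genes, 3 fell (3 adjusted over the list alone; median -0.86, adjusted p = 0.0455), namely the fatty acid transporter CD36 (-2.33), FABP4 (-1.24) and PLIN4 (-0.86), all under 6 CPM, and this call was lost without hairpin 3 (adjusted p = 0.067). It was also lost without the induced hairpin 1 library (0.071) or the uninduced hairpin 2 (0.1) or hairpin 3 (0.051) library, with relative log expression scaling (0.058) and with no filter on low counts (0.21). Of the 11 lists that camera called in Hs578, fry called 10 and not the immediate early list (adjusted p = 0.0567).

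The lists of cell identity were not called in Hs578 by camera, while fry called the luminal breast list as lower (adjusted p = 0.00671, against 0.0782 by camera). Of 15 epithelial genes, 4 rose, among them SPINT1 (1.39), LSR (1.16) and KRT7 (0.94), all from low levels (1 adjusted over the list alone). The epithelial list as a whole did not rise (median -0.25, camera adjusted p = 0.811). Of 24 mesenchymal genes, 4 rose, such as NID2 (1.12), and 2 fell, PDGFRA (-1.21) and ITGB3 (-0.91), the same numbers as adjusted over the list alone. Of 34 mesenchymal transcription factors, 4 rose, including OSR1 (1.44) and HIC1 (0.98), and 3 fell, including SOX9 (-0.86) (4 and 1 adjusted over the list alone). Of 14 basal breast genes, 4 rose, including KRT14 (1.55) and EN1 (1.86, adjusted p = 0.025, 0.052 with the replicate block and 2.1e-05 to 0.25 across the alternatives), and 2 fell, including the integrin ITGA6 (-1.12) (4 and 3 adjusted over the list alone). Of 12 luminal breast genes, 4 fell, including PGR (-1.27), ERBB3 (-0.75) and ALCAM (-0.5), the same number as adjusted over the list alone.

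Proliferation and signalling lists were mixed in Hs578. Of 36 S-phase genes, 9 rose, including CCNE1 (0.67), CLSPN (0.62) and CDT1 (0.48), and none fell (9 adjusted over the list alone; camera adjusted p = 0.0642). Of 34 mitosis genes, 3 rose, including UBE2C (0.59) and AURKB (0.53), and 2 fell, including ECT2 (-0.64) (2 and 2 adjusted over the list alone). Of 19 YAP targets, 7 fell, including FJX1 (-0.75), ASAP1 (-0.69) and MYOF (-0.54) (8 adjusted over the list alone; camera adjusted p = 0.0515). Of 32 interferon genes, 2 rose, IFI27 (2.28) and ISG15 (1.06, adjusted p = 0.038, 0.061 with the replicate block and 0.0012 to 0.33 across the alternatives), and 4 fell, including RSAD2 (-1.57) (1 and 3 adjusted over the list alone). Of 21 inflammatory genes, 2 rose, NFKBIA (0.6) and IER3 (0.52), and 2 fell, including PTGS2 (-1.79), with the same numbers adjusted over the list alone. Of 17 endoplasmic reticulum stress genes, 6 rose, including CRELD2 (0.61) and PDIA3 (0.54), and 3 fell, including EDEM1 (-0.5) (6 and 5 adjusted over the list alone). Of 13 Wnt targets, 2 rose, NOTUM (1.15) and LEF1 (0.46), and 1 fell, TNFRSF19 (-0.61), the same as adjusted over the list alone. Of 19 SWI/SNF subunits, 4 rose and 1 fell (5 and 2 adjusted over the list alone). SMARCD3 (0.49), BRD9 (0.43) and SMARCB1 (0.33, SE 0.082, adjusted p = 0.0089) were among those that rose. Of 21 p53 targets, 1 rose and 1 fell, as over the list alone.

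Markers of other tissues stayed mostly uncalled in Hs578. A single gene rose among 7 blood cell, 6 skeletal muscle, 8 bone and cartilage and 10 neural genes each, and none of 6 endothelial genes was called over all genes by edgeR. The medians of the blood cell list (0.54, against a mean of -0.14) and of the mesenchymal transcription factors (-0.05, against a mean of 0.09) differed in sign from their means, and camera put both lists in the higher direction without a call (adjusted p = 0.321 and 0.936). The blood cell list was called as higher by fry (adjusted p = 0.0385).

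**Figure D2:**
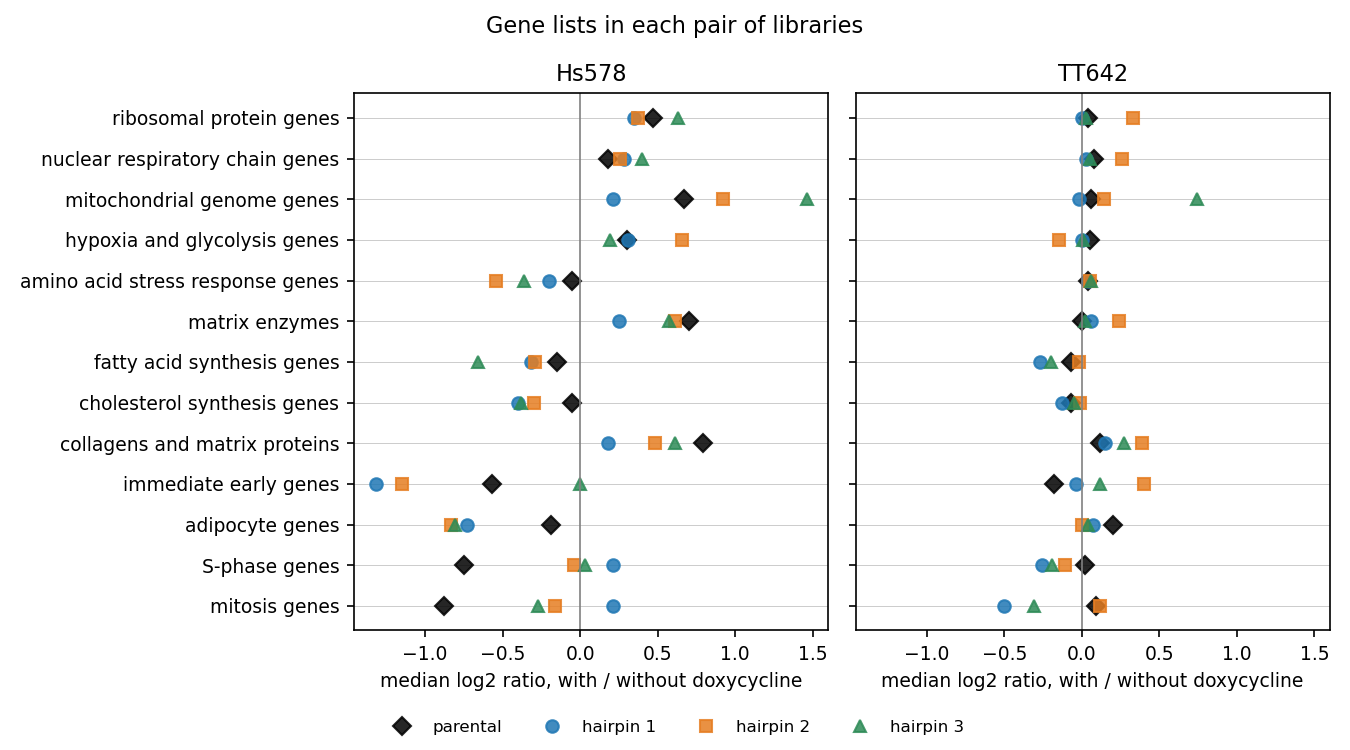
Median log2 ratio with over without doxycycline of the genes in 13 lists, in each pair of libraries, for Hs578 (left) and TT642 (right) on 1 scale, with 1 symbol per pair, black diamonds for parental cells and coloured symbols for hairpins 1 to 3. In Hs578 the parental S-phase and mitosis medians, -0.75 and -0.88, lie below those of all hairpins, while collagens and matrix proteins are higher in all 4 Hs578 pairs.

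In TT642 hairpin lines, few genes passed the threshold. CD82, a membrane tetraspanin, rose from 9.13 ± 1.67 to 23.2 ± 0.344 CPM (SD, n = 3; log2 fold change 1.35, SE 0.14, adjusted p = 0.0015), and CENPT, a kinetochore protein, rose from 17.6 ± 1.67 to 28.6 ± 3.28 CPM (0.71, SE 0.11, adjusted p = 0.044). ENO3, the muscle enolase, fell from 86.3 ± 4.31 to 47.4 ± 4.87 CPM (-0.86, SE 0.098, adjusted p = 0.0025). Parental TT642 cells held 5.07 and 6.58 CPM of CD82, 18.2 and 16.3 of CENPT and 124 and 105 of ENO3 without and with doxycycline. The other called gene, IL23A (-2.44, SE 0.365), was singled out after its values were seen. Below the threshold lay KIAA1644 (-0.64, adjusted p = 0.067), TYMP (-0.55), IFIT2 (-1.45), S100P (-0.75) and GINS4 (-0.69, adjusted p = 0.082 for these 4), C10orf54 (0.82) and VTI1A (-0.6, adjusted p = 0.11 for both). SMARCB1 did not change detectably (0.03, SE 0.085, adjusted p = 1).

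By edgeR, 2 genes rose and 2 fell in TT642, against 1098 genes with an unadjusted p under 0.05 and 74 calls by DESeq2. With log2(FPKM + 1) 2 rose and 10 fell by limma, and with log2(FPKM + 0.1) 2 rose and 0 fell. With the replicate block, 24 rose and 22 fell, and KIAA1644, TYMP, S100P, GINS4, C10orf54 and VTI1A were then called (adjusted p = 0.0064 for KIAA1644 and 0.041 for C10orf54, with ranges of 6.7e-05 to 0.58 and 0.0039 to 0.7 across the alternatives). No gene was called without hairpin 2 or without hairpin 3, 1 without hairpin 1 and 2 without the uninduced hairpin 1 library. The call of CD82 was lost without hairpin 2 (adjusted p = 0.077) or hairpin 3 (0.071), with a range of 4.3e-16 to 0.077 across the alternatives, that of ENO3 without any 1 of the 3 hairpins (0.071 to 0.21) or with log2(FPKM + 0.1) (0.14), and that of CENPT in 10 of its alternatives, with an adjusted p of 4.5e-05 to 0.42 across the alternatives.

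Small shifts of gene lists were called in TT642 by camera with its preset correlation, but none of the 32 lists with an estimated correlation (smallest adjusted p = 0.66) or by fry. Interferon genes (median -0.41, camera adjusted p = 1.23e-09), S-phase genes (-0.21, 5.94e-10), mitosis genes (-0.17, 2.66e-06), inflammatory genes (-0.18, 0.015), fatty acid synthesis genes (-0.12, 0.00195) and cholesterol synthesis genes (-0.06, 0.0156) were lower than other genes. Mitochondrial genome genes (0.29, 0.00195), collagens and matrix proteins (0.24, 0.00504), endoplasmic reticulum stress genes (0.15, 3.11e-05), nuclear respiratory chain genes (0.13, 0.000115), ribosomal protein genes (0.12, 0.00131) and matrix enzymes (0.12, 0.0229) were higher. None of their members was called over all genes by edgeR, and 8 interferon, 3 S-phase and 3 fatty acid genes fell and 3 matrix enzymes, 1 endoplasmic reticulum stress and 1 nuclear respiratory chain gene rose adjusted over the list alone. The interferon median was -1.5 in hairpin 2, -0.18 and -0.07 in hairpins 1 and 3, and -0.9 in the parental pair. The ribosomal and nuclear respiratory chain calls were lost without hairpin 2 (adjusted p = 0.85 and 0.34) or its induced library (0.58 and 0.23), and the mitochondrial genome call without hairpin 3 (0.51) or its induced library (0.32), in which the mitochondrial share was 3.98% against 2.6% uninduced. The collagen, inflammatory and matrix enzyme calls were lost without hairpin 2 (0.07, 0.23 and 0.1) or its uninduced library (0.1, 0.094 and 0.12), the last 2 also without its induced library (0.08 and 0.074), and the collagen and matrix enzyme calls without the induced hairpin 3 library (0.15 and 0.073). The cholesterol call was lost without hairpin 1 (0.2), either of its libraries (0.099 and 0.055), hairpin 3 (0.35) or its induced library (0.34).

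Averaged over both lines, the called genes with large changes were the following. COL1A1 (1.64, SE 0.44), IL32 (1.29, SE 0.22), CD82 (1.25, SE 0.092, adjusted p = 1.9e-05), TGFBI (1.24, SE 0.16) and ACTA2 (1.06, SE 0.21) rose. CALCRL, a peptide hormone receptor (-1.26, SE 0.17), ZNF704 (-1.16), the adhesion receptor GPR56 (-1.08), the transcription factors SOX9 (-1.03) and KLF4 (-1, SE 0.14) fell. The effects of IL32 and CALCRL differed between the lines by the test of the difference, and IL32 stood at 3.47 CPM without and 3.58 CPM with doxycycline in the TT642 hairpin lines. CD82 was higher in all 6 hairpin pairs, by 0.81 to 1.63 on the log2 scale, and by 1.02 and 0.37 in the parental pairs of Hs578 and TT642. KLF4 was lower in all 6, by values from -0.44 to -1.59, and by -0.73 and -0.3 in the parental pairs.

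Camera called 12 lists over both lines with its preset correlation, but none with an estimated correlation (smallest adjusted p = 0.36). Those called as higher held rises of 25 of 33 ribosomal protein genes (32 adjusted over the list alone), 19 of 33 nuclear respiratory chain genes with 1 lower (22 and 1), 9 of 13 mitochondrial genome genes (12), 11 of 27 matrix enzymes (12), 10 of 38 matrix proteins (10) and 7 of 29 hypoxia genes with 1 lower (12 and 2). Examples were RPS28 (0.48), COX6C (0.41), MT-ATP6 (0.77), P4HA1 (0.68) and COL3A1 (0.93), while VEGFA fell (-0.48). Members fell in the fatty acid list (4 of 11, with 7 over the list alone, SCD at -0.59), the cholesterol list (10 of 24, with 13 lower and 2 higher over the list alone, SQLE at -0.4), the amino acid stress list (5 of 32, with 8, SESN2 at -0.65), the immediate early list (5 of 17, with 5, NR4A3 at -1.42), the mitosis list (4 of 34, with 0) and the interferon list (3 of 32 with 1 higher, with 2 and 0). Of these 12 lists, the amino acid stress, immediate early and hypoxia lists had medians of opposite sign in the lines (-0.32, -1.02 and 0.4 in Hs578, and 0.05, 0.16 and -0.04 in TT642), and SESN2 stood at 526 CPM with and without doxycycline in TT642 hairpin lines. Of the 12 lists fry called 7, and not the hypoxia (adjusted p = 0.0755), amino acid stress (0.184), interferon (0.194), mitosis (0.37) and immediate early (0.194) lists, and it also called the adipocyte (0.0014), endoplasmic reticulum stress (0.0317) and luminal (0.0317) lists. By camera, the luminal breast list (median -0.15, adjusted p = 0.0993, no member called, nor over the list alone) was called as lower with the replicate block (0.0291). The immediate early call was lost with log2(FPKM + 1) (adjusted p = 0.16) and log2(FPKM + 0.1) (0.17), without hairpin 1 (0.27) or the Hs578 libraries of uninduced hairpin 1 (0.11), induced hairpin 1 (0.058) and uninduced hairpin 2 (0.088). The mitosis call was lost without hairpin 3 (0.26), the induced Hs578 hairpin 3 library (0.055) or the induced TT642 hairpin 1 library (0.11).

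Over both lines 1208 genes rose and 914 fell by edgeR, 37 and 25 of them at least 2-fold. More genes fell than rose under some settings here too, with 1030 higher and 1119 lower under relative log expression scaling, 1198 and 1396 by DESeq2, 786 and 1653 with log2(FPKM + 1), 730 and 1436 with log2(FPKM + 0.1), and 75 and 118 without hairpin 2 and 82 and 97 without hairpin 3. The total of 2122 was 1130, 193 and 179 without hairpins 1, 2 and 3. It was 1026, 3185, 1217, 1341 and 1365 without the Hs578 libraries of uninduced hairpin 1, induced hairpin 1, induced hairpin 2, uninduced hairpin 3 and induced hairpin 3, and 1232 and 1392 without the uninduced TT642 libraries of hairpins 1 and 2. Of the 64 called genes named by the rule, 20, 44 and 42 were no longer called without hairpins 1, 2 and 3, and 4 to 18 without a single library, while 12 were called throughout, among them CD82, CALCRL, KLF4, TGFBI, NR4A3 and SCD. With the replicate block ATF3, FOSB, IFIT2, MT-ATP8 and PDGFRA were no longer called (adjusted p = 0.053, 0.059, 0.19, 0.081 and 0.09), nor were COL1A1 and SOX9 with no filter on low counts (0.056 and 0.069).

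The effects of the 2 lines correlated weakly across genes. The log2 fold changes of 14035 genes correlated at 0.06 (Pearson) and 0.15 (Spearman), and 56.3% had the same sign; these values are across genes, which are not independent replicates. Over the 4118 genes called in Hs578 the correlation was 0.13 (Pearson) and 0.28 (Spearman), and 2600 genes (63.1%) had the same sign. Of the called genes, CD82 and CENPT, the pair called higher in TT642, were also called higher in Hs578 (0.305 expected, Fisher's exact test p = 0.023, one-sided for more shared genes), and none was shared among the lower genes (0.282 expected, p = 1). With the replicate block 6 genes were shared among the higher (4.11 expected, one-sided Fisher's exact test p = 0.22) and 10 among the lower (3.86 expected, p = 0.0022). Fisher's test takes genes as independent, which they are not, and the shared calls are not net of doxycycline. Pairs of different hairpins correlated at 0.66 to 0.72 within Hs578 and at 0.18 to 0.43 within TT642, and the parental pair with hairpins of its line at 0.31 to 0.64 and at 0.06 to 0.3. The hairpin with the same number in the other line gave -0.03 to 0.26 and hairpins with different numbers -0.08 to 0.23.

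By the test of the difference between lines, IL32 (2.48, SE 0.45, adjusted p = 0.016), TAGLN (2.37, SE 0.47, adjusted p = 0.033) and TNC (1.89, SE 0.37, adjusted p = 0.027) had a more positive effect in Hs578 than in TT642. GDF15 (-2.36, SE 0.42, adjusted p = 0.023), SESN2 (-1.3, SE 0.18, adjusted p = 0.004) and CALCRL (-2, SE 0.35, adjusted p = 0.013) had a more negative one. In all 387 genes differed upwards and 348 downwards by edgeR (875 and 888 with the replicate block). The split was 361 and 390 with relative log expression scaling, 664 and 740 by DESeq2, 337 and 781 with log2(FPKM + 1), 269 and 567 with log2(FPKM + 0.1), and 337 and 344 with no filter on low counts. Downward differences were also more numerous without hairpin 2 (11 and 27) or hairpin 3 (0 and 2) and without 8 of the 12 single libraries. Of the 32 lists, 7 had a higher and 4 a lower effect in Hs578 by camera, none with an estimated correlation (smallest adjusted p = 0.61) and 1 by fry. The count of 735 fell to 123, 38 and 2 without hairpins 1, 2 and 3. Without the uninduced Hs578 libraries of hairpins 1, 2 and 3 it was 93, 476 and 158, and without the induced ones 2082, 193 and 172. Without the uninduced TT642 libraries of hairpins 1 and 3 it was 86 and 58, and without the induced ones 198 and 237. None of the 37 called genes named by the rule was called in every leave-out, and 26, 33 and 36 lost their call without hairpins 1, 2 and 3.

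Doxycycline alone was followed in the parental cells. Over both lines, the cystine transporter subunit SLC7A11 (log2 fold change -0.96, SE 0.14, adjusted p = 0.048) and PHACTR2 (-0.83, SE 0.11, adjusted p = 0.021) fell. SLC7A11 went from 577 to 165 CPM in Hs578 and from 113 to 105 in TT642, and PHACTR2 from 126 to 45 and from 30.2 to 26.7. Next, short of the threshold at an adjusted p = 0.058, were C6orf57 (1.02), the matrix protease MMP14 (0.62), ZP3 (0.96), the AMPK subunit PRKAA1 (-0.75), SERPINF1 (1.99), LTBP4 (0.88), and the RNA-binding proteins HNRNPM (-0.64) and BCLAF1 (-0.66). These 8 were called with the replicate block (adjusted p = 0.014 for PRKAA1 and 0.041 for LTBP4, with ranges of 0.00029 to 0.23 and 0.00012 to 0.23 across the alternatives).

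No gene rose and 2 fell with doxycycline in parental cells by edgeR, against 2131 with an unadjusted p under 0.05, 151 higher and 119 lower by DESeq2, and 77 higher and 86 lower with the replicate block. Tests of each line alone, chosen after the data were seen, called 450 higher and 577 lower genes in parental Hs578 and 0 in parental TT642 by edgeR, with 3689 and 138 at an unadjusted p under 0.05. These tests set single parental libraries against each other, taken to vary like the hairpin groups, and so show neither an effect of doxycycline nor a difference between the lines. There were 40 calls without hairpin 1, 1 without hairpin 2 and none without hairpin 3, whose libraries enter only the estimate of the spread. SLC7A11 and PHACTR2 were not called without hairpin 2 (adjusted p = 0.075 for both) or hairpin 3 (0.15 for both), nor with log2(FPKM + 1) (0.077 for both) or log2(FPKM + 0.1) (0.11 for both). SLC7A11 was also not called with relative log expression scaling (0.06), at least 1 CPM in 3 libraries (0.059), TMM without mitochondrial genes (0.058) or a fit without robust moderation (0.07). By camera with its preset correlation 11 lists were called, but none with an estimated correlation (smallest adjusted p = 0.38) or by fry. S-phase genes (median -0.36, camera adjusted p = 1.52e-12; 19 of 36 lower adjusted over the list alone), mitosis genes (-0.39, 6.53e-08; 1 of 34) and interferon genes (-0.46, 0.00138) were lower. Collagens and matrix proteins (0.49, 1.64e-07; 5 of 38 higher adjusted over the list alone) and matrix enzymes (0.38, 4.23e-05; 9 of 27) were higher. So were ribosomal protein (0.26), mitochondrial genome (0.33, adjusted p = 0.0449, 0.11 with the replicate block, 0.16 without hairpin 2 and 0.065 with no filter on low counts), inflammatory (0.24, not called with no filter, 0.14), endoplasmic reticulum stress (0.15), hypoxia (0.14) and nuclear respiratory chain genes (0.14), none of them with a called member. The parental medians of Hs578 and TT642 were -0.75 and 0.02 for S-phase, -0.88 and 0.09 for mitosis, -0.14 and -0.9 for interferon, 0.79 and 0.12 for matrix protein, 0.7 and 0 for matrix enzyme and 0.93 and -0.25 for inflammatory genes. They were 0.47 and 0.04 for ribosomal protein, 0.67 and 0.06 for mitochondrial genome, 0.21 and 0.13 for endoplasmic reticulum stress, 0.3 and 0.05 for hypoxia and 0.18 and 0.08 for nuclear respiratory chain genes. The mitochondrial share of counts went from 2.73% to 4.16% in parental Hs578 and from 3.28% to 3.31% in parental TT642. Parental Hs578 and TT642 cells differed in size of change: 433 and 29 of 10351 genes moved at least 2-fold in their single pairs, a difference that was not tested. In Hs578 this was more than in the pairs of hairpins 1, 2 and 3, where 169, 274 and 396 genes moved as far. In TT642 the hairpin pairs had 55, 162 and 23 such genes.

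The hairpin effect net of the parental doxycycline effect gave no called gene by edgeR as a mean over both lines. PRRX1 had a net log2 fold change of -2.2 (SE 0.5, adjusted p = 0.51, and 0.024 by DESeq2, over a range of 0.024 to 1 across the alternatives). The genes with the smallest p were TNFRSF10D, a death ligand receptor (0.68), CENPT (0.77), ABCA3 (-1.05), NCOA5 (0.68), NQO1 (-0.69), HNRNPM (0.61), CLN6 (0.8), ZWINT (0.84), NUTF2 (0.56) and SYT5 (-3.67, under 1 CPM in Hs578), each with an adjusted p = 0.45. HNRNPM stood at 333 CPM without and 142 with doxycycline in parental Hs578 and at 348 and 340 in the Hs578 hairpin lines. By edgeR 0 genes were called and 960 had an unadjusted p under 0.05, while DESeq2 called 16. In Hs578 alone 41 genes were called higher and 16 lower, with 1996 at an unadjusted p under 0.05, and in TT642 alone 0 by edgeR, with 179. These tests of each line were chosen after the data were seen and rest on single parental libraries.

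Net of the parental effect, camera called 6 lists with its preset correlation, but none with an estimated correlation (smallest adjusted p = 0.7), and fry called none. Relative to parental cells, S-phase genes (median 0.33, camera adjusted p = 2.07e-12; 11 of 36 higher adjusted over the list alone), mitosis genes (0.27, 0.000805) and nuclear respiratory chain genes (0.12, 0.0239) had a higher effect. Inflammatory genes (-0.42, 0.00065; 2 of 21 lower adjusted over the list alone), fatty acid synthesis genes (-0.24, 0.00196; 1 of 11) and amino acid stress genes (-0.18, 0.0138) had a lower one. In Hs578 the S-phase median was -0.75 in the parental pair and 0.21, -0.04 and 0.03 in hairpins 1, 2 and 3, and in TT642 it was 0.02 in the parental pair and -0.26, -0.11 and -0.19 in the hairpins. The mitosis median was -0.88 in parental Hs578 and 0.21, -0.16 and -0.27 in its hairpins, and 0.09 in parental TT642 and -0.5, 0.12 and -0.31 in its hairpins. The amino acid and respiratory chain calls were lost without hairpin 2 (adjusted p = 0.11 and 0.24) or hairpin 3 (0.071 and 0.057). The amino acid call was also lost without the uninduced Hs578 hairpin 2 library (0.15), and the respiratory chain call without the Hs578 libraries of uninduced hairpin 1 (0.083), induced hairpin 2 (0.056) and induced hairpin 3 (0.14) or the induced TT642 hairpin 2 library (0.21).

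Before induction, hairpin lines and parental cells were compared to see whether they started alike. MARCKS, a membrane-bound protein kinase C substrate, was lower in hairpin lines (log2 fold change -1.79, SE 0.13, adjusted p = 2.8e-05), as were the endopeptidase MME (-2.26), the nuclear receptor corepressor NRIP1 (-1.81), MCTP1 (-1.73) and ZNF804A (-1.64). The gap lay in TT642, where MARCKS stood at 226 CPM in parental cells and 19.9 ± 3.62 in hairpin lines (SD, n = 3), against 1130 and 1070 CPM in Hs578. NRIP1 stood at 22.2 and 2.22 CPM in TT642 and at 92.6 and 75.1 in Hs578. PRRX1 did not differ detectably (-0.17, SE 0.34, adjusted p = 0.94).

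By edgeR, none of the genes was higher and 29 were lower in uninduced hairpin lines, with 1288 at an unadjusted p under 0.05 and 7 higher and 76 lower by DESeq2. With log2(FPKM + 1) 1 was higher and 9 were lower, and with log2(FPKM + 0.1) 1 and 5. The 29 became 9 without hairpin 3, and 15, 16 and 16 without the uninduced libraries of Hs578 hairpin 2, Hs578 hairpin 3 and TT642 hairpin 3. ZNF804A was not called without hairpin 2 (adjusted p = 0.1), hairpin 3 (0.15) or any of those 3 libraries (0.05 to 0.058), nor with log2(FPKM + 1) (0.58) or log2(FPKM + 0.1) (0.28). MME was not called with log2(FPKM + 1) (0.056) and MCTP1 not with log2(FPKM + 0.1) (0.14). S-phase (0.17), mitosis (0.21), endoplasmic reticulum stress (0.12) and ribosomal protein genes (0.1) were higher and interferon (-0.44), inflammatory (-0.19) and p53 target genes (-0.11) lower by camera, but no list was called with an estimated correlation (smallest adjusted p = 0.7) or by fry. The p53 call was lost without any 1 hairpin (adjusted p = 0.078 to 0.12) or the uninduced libraries of hairpins 1 and 3 in Hs578 (0.051 and 0.1) and of hairpins 1 and 2 in TT642 (0.057 and 0.11), with no filter on low counts (0.053) and with log2(FPKM + 1) (0.15) or log2(FPKM + 0.1) (0.17). The ribosomal call was lost without hairpin 2 (0.12) or its uninduced Hs578 library (0.069), and the inflammatory call without hairpin 3 (0.081).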

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

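The tests of the slope, of Hs578 transcripts, of hairpin activity before induction, of the splits that part all pairs and of the splits of TT642 alone were chosen after the results were seen.

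The hairpin effect differed between the 2 lines for 735 genes by the test of the difference itself, and each gene's value in this paragraph is a log2 fold change in Hs578 minus that in TT642. Matrix, contractile and cytokine genes with a more positive effect in Hs578 were IL32 (2.48), TAGLN (2.37), TNC (1.89), SERPINH1 (1.26), BMP1 (1.22), TPM2 (0.94), MYL9 (0.92) and PLOD1 (0.9). So were the interferon and inflammatory genes ISG15 (1.85), ICAM1 (1.77), IRF7 (1.06) and NFKBIA (0.94), the hypoxia genes ANKRD37 (1.56), SLC16A3 (1.08) and BNIP3 (0.78), and the S-phase genes CLSPN (0.93), CDT1 (0.69) and FEN1 (0.68). NDUFA2 (0.83), RPL35 (0.7), RPLP1 (0.63) and NDUFA6 (0.51) completed the higher ones. Stress and immediate early genes with a more negative effect in Hs578 were ATF3 (-3.05), GDF15 (-2.36), NR4A3 (-1.94), PTGS2 (-1.79), SESN2 (-1.3) and CHAC1 (-1.28). So were PLEKHG1 (-2.15), SDC4 (-2.08) and CALCRL (-2), the cholesterol genes LSS (-0.75) and SQLE (-0.57), and the YAP targets ASAP1 (-0.49) and PTPN14 (-0.48). With the replicate block ATF3 (adjusted p = 0.053) and PTGS2 (0.11) were no longer called. With no filter on low counts ISG15, ATF3, NDUFA6, SERPINH1 and PTGS2 were not called (0.054 to 0.071), nor were PLEKHG1, SDC4, RPL35, CDT1, FEN1, BNIP3, SQLE and ICAM1 with at least 1 pseudocount of the FPKM (0.051 to 0.15). SDC4, NDUFA6, PTPN14 and ICAM1 were not called without robust moderation (0.051 to 0.054), nor NDUFA6 with relative log expression scaling or TMM without mitochondrial genes (0.051 for both).

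Camera called 11 lists for the difference with its preset correlation, but none with an estimated correlation (smallest adjusted p = 0.61), and fry called only the adipocyte list (0.0109), which is not among them. The median difference of the 11 lists was 0.6 for mitochondrial genome, 0.42 for matrix enzyme, 0.41 for hypoxia and glycolysis, 0.34 for ribosomal protein, 0.33 for S-phase, 0.24 for interferon and 0.17 for nuclear respiratory chain genes. It was -1.13 for immediate early, -0.36 for amino acid stress response, -0.36 for YAP target and -0.32 for cholesterol synthesis genes. These differences are not net of doxycycline. The parental Hs578 and TT642 medians were 0.67 and 0.06 for mitochondrial genome, 0.7 and 0 for matrix enzyme and 0.47 and 0.04 for ribosomal protein genes. They were ordered against the hairpin difference only for S-phase (-0.75 and 0.02), YAP target (0.02 and -0.13) and cholesterol genes (-0.05 and -0.07). The interferon list was not called with the replicate block (adjusted p = 0.078), and without hairpin 2 its median was -0.03. Without hairpin 2 the immediate early (0.13), mitochondrial genome (0.15), YAP (0.19) and cholesterol (0.13) calls were lost as well, and without hairpin 3 the matrix enzyme (0.053) and nuclear respiratory chain (0.092) calls.

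Other splits of the hairpin libraries were compared with the real one. Within a line, 10 splits are too few for a share under 0.05: the real split gave 4118 genes in Hs578 and the highest other 0, and in TT642 the values were 4 and 2, so that 1 of 10 splits gave as many in each line. Over both lines 1 of 80 splits, the real one with 2122 genes, gave as many, and the highest other gave 1580. Among all 32 splits that part the 6 pairs, as the real one does, 1 gave as many and the highest other gave 1796. These shares are under 0.05 only for the case of no effect in either line, and they exclude chance for neither line by itself: the 24 of the 32 splits that differ from the real one within Hs578 gave 0 genes by edgeR, and 10 splits of Hs578 are too few. With the real split kept in Hs578, 20 splits of TT642 are too few as well: 1 of 20 gave as many, and the highest other gave 2080, so that a part of TT642 in the count was not shown. For the difference between lines, 5 of 80 splits gave at least 735 genes, the highest other 1796, as did 5 of 32 that part the pairs and 15 of 20 of TT642, the highest other 2122 in both. These counts do not test the difference. Each split that called a gene for it keeps the real split within Hs578, so that the Hs578 effect stays in the difference whatever the labels in TT642, and exchanging the labels of 1 line turns the difference into the mean, which gives the 2122. Of the 80 splits, 72 gave 0 genes by edgeR and 7 others keep the real split within Hs578.

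Genes called with doxycycline in the Hs578 hairpin lines moved the same way in parental Hs578 cells, for 83.3% of 4118 genes. Genes called from 2 hairpins kept their sign in the hairpin left out for 95.1%, 97.6% and 97.4%. In the parental pair the shares were 88.7%, 80% and 86.3%. This gap cannot decide whether doxycycline or a culture difference acting without a hairpin is the whole cause, since a single parental pair gives no spread. Knockdown of PRRX1 as the whole cause was examined by the slope of the parental change on the hairpin change. This slope was 0.656, against 0.01 to 0.17 for 6 pairs of Hs578 libraries without doxycycline. The parental pair thus followed the hairpin effect further than those pairs, but a single pair cannot decide this cause either. The slope was taken after the sign share had been seen, and that share was not clearly beyond those pairs, which reached 82.1%. The shares were not measured alike, since those pairs were scored in their better orientation. Each of them also holds an uninduced hairpin library that enters the hairpin effect. A part played by each, and the state of the cultures, remain open, and the parental side may rest on the state of a single pair of libraries. No line with a hairpin against another target was sequenced. Effects of switching on any hairpin therefore cannot be told from those of lowering PRRX1.

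Parental TT642 cells, a single library without doxycycline taken to vary like the hairpin groups, stood apart from the TT642 hairpin lines before induction, with 107 genes lower and 22 higher in the hairpin lines. Hs578 cells in the parental culture are argued against for these genes as a set, since 42 transcripts abundant in Hs578 showed a median Hs578 share of 0.0074% (0.47% at most), while the 70 genes with a level in Hs578 needed a median of 21.3% (0.24% at least). For 2 of the 70 genes the share needed was no more than the highest seen, so these are not excluded singly, and the other 37 of the 107 lay under 1 CPM in Hs578. Hairpin activity before induction stays open: the 107, 208 and 100 genes lower in TT642 hairpin lines when hairpin 1, 2 or 3 was left out moved on induction of the line left out by a median of -0.1, -0.27 and 0.05, against a gap to parental cells of -2.23, -1.28 and -2.4 before it. The derivation of the hairpin lines from a part of the parental culture could also give such a difference and was not tested, and the gap may belong to the single parental library.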

How the results depend on the processing

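The tests without robust moderation, with TMM scaling without mitochondrial genes and of each line alone were chosen after the data were seen. Over 25 settings, 3727 of 4674 values of named genes other than PRRX1 kept their direction and their side of the threshold, 885 were no longer called, 61 became called and 1, that of FSTL1, changed sign. Over 23 settings, 1176 of 1265 values of called lists were kept and 89 were no longer called. Of 154 counts of genes, 82 lay within 1.5 times the reported value. These include counts of 0 that stayed at 0, as for the net effect in most settings. Unless a reason is given, the cause was not tested. Leaving out a library lowers the number of replicates, and a hairpin group left with 2 libraries relies on the spread of the other groups.

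With a fold of at least 2 required, 414 genes were called in Hs578, 2 in TT642, 62 over both lines, 140 for the difference and 0 for doxycycline in parental cells, where 2131 had an unadjusted p under 0.05 and DESeq2 called 270. DESeq2 called 74 genes in TT642, 1404 for the difference, 16 for the net effect and 83 between hairpin and parental lines, with 25 shared between the lines. It called PRRX1 in TT642 (-2.04) and in the net effect (-2.22). PRRX1 in TT642 was also called without robust moderation (-2.03) and with log2(FPKM + 1) (-2.18). For doxycycline in parental cells, 1 gene was called without robust moderation, with relative log expression scaling, with at least 1 CPM in 3 libraries, with TMM without mitochondrial genes and with log2(FPKM + 1). With no filter on low counts 8 genes were called in TT642, 24 for doxycycline in parental cells, and 4 were shared between the lines. With the libraries of a comparison alone 2 were called in TT642 and 1 was shared.

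With log2(FPKM + 1) 12 genes were called in TT642, 1118 for the difference, 337 of them higher and 781 lower, 3 for the net effect and 10 between hairpin and parental lines. With log2(FPKM + 0.1) the counts were 2 in TT642, 1 for the net effect, 6 between hairpin and parental lines and 1 shared. PRRX1 with doxycycline in parental cells changed sign to -0.03 with both pseudocounts, and FSTL1 over both lines stood at 0 with log2(FPKM + 1). In Hs578 alone 1027 genes were called with doxycycline in parental cells, 57 for the net effect and 0 between hairpin and parental lines, and in TT642 alone 0, 0 and 129 by edgeR, with 268, 138 and 179 genes at an unadjusted p under 0.05 behind the counts of 0. These tests compare single parental libraries, assumed to vary like the hairpin groups.

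With the replicate block, 46 genes were called in TT642, 1763 for the difference and 163 for doxycycline in parental cells, and 16 were shared between the lines. Apart from the calls given with their results, the block changed no other call of a named gene or list. For hairpin against parental lines without doxycycline the block could not be fitted, since it lies between derived lines. With an estimated correlation camera called 0 of the 32 lists in each of the 7 comparisons, and fry called 12 in Hs578, 10 over both lines, 0 in TT642, for doxycycline, for the net effect and for hairpin against parental lines, and 1 for the difference.

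Leaving out each hairpin or library in turn gave 840 to 4768 genes in Hs578, 0 to 6 in TT642, 179 to 3185 over both lines, 2 to 2082 for the difference, 0 to 40 for doxycycline in parental cells, 9 to 34 between hairpin and parental lines and 0 to 4 shared genes. The called lists numbered 7 to 13 in TT642. PRRX1 ran from -2.65 to -1.98 in Hs578, from -2.55 to -1.69 in TT642 and from -0.97 to 0.3 for the difference, with 0.27 without the induced TT642 hairpin 3 library. Its adjusted p in TT642 by edgeR ran from 0.004 to 0.87, so whether it was called there depended on what was left out. The net effect gave 0 genes by edgeR in every such setting, with 960 at an unadjusted p under 0.05 over all libraries. The fit to the libraries of a comparison was not applicable to the 3 comparisons with parental cells, and a fold threshold or DESeq2 not to lists. No group held enough libraries to test a single library against the rest. Counting depth limits genes of low level, and 2457 genes had no count.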

Other observations

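The genes in this part were chosen after their values were seen, and no tests were run on them. The 2 lines differed widely without doxycycline, in 4 libraries each, of which 1 was parental (mean CPM ± SD, n = 4, over parental and derived cells together). The mesenchymal filament gene VIM stood at 4250 ± 148 in Hs578 and 10300 ± 472 in TT642, and PRRX1 at 267 ± 30.3 and 1350 ± 119. FN1, the gene of the matrix protein fibronectin, stood at 10700 ± 896 in Hs578 and 0.754 ± 0.406 in TT642. The epithelial keratins KRT8 and KRT18 stood at 34.7 ± 3.37 and 333 ± 49.1 in Hs578 and at 0.652 ± 0.326 and 0.36 ± 0.221 in TT642. The neural transcription factors TBR1 and SOX21 stood at 15.4 ± 3.42 and 32 ± 5.96 in TT642 and at 0.0739 and 0.308 in Hs578. The proliferation marker MKI67 stood at 599 ± 39.8 in Hs578 and 60.7 ± 16.3 in TT642.

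Some subunits of the SWI/SNF chromatin remodelling complex also differed between the lines. Others were similar, such as BRD9 (38.9 CPM in Hs578 and 37.5 in TT642), PBRM1 (149 and 140) and ACTL6A (88.8 and 83). SMARCB1, the subunit commonly lost in rhabdoid tumours, stood at 95.5 ± 7.67 CPM in Hs578 and 36 ± 5.3 in TT642, and counts per gene do not tell whether its transcript was intact. The ATPase gene SMARCA2 stood at 68.6 ± 3.99 in Hs578 and 0.264 ± 0.0848 in TT642, while SMARCA4, which encodes the alternative ATPase, stood at 278 ± 5.31 and 306 ± 4.9. SMARCD3 stood at 10.1 ± 1.1 and 55.9 ± 8.77, and ARID1A at 153 ± 4.74 and 491 ± 42.2.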
